A study of Homo sapiens with 6 samples.

How the data were processed

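Gene expression was measured on 6 Affymetrix arrays from human dendritic cells (antigen-presenting cells) grown from monocytes for 5 days with GM-CSF and IL-4, 3 without and 3 with 10 ug/mL etanercept. Etanercept is a soluble fusion protein of the TNF receptor 2 ectodomain and an antibody Fc part that binds and neutralises TNF. Total RNA was amplified once and labelled with biotin, per the labels' protocols. The labels number each group 1 to 3 and state that the controls are paired with the treated samples. They do not state what a pair shares (a donor, a day or a batch), nor whether replicates came from separate donors, so the p-values measure the spread between these pairs only.

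The deposited table holds 22277 probe sets, of which 62 are Affymetrix controls, as linear ratios from 0.01 to 70.01. GCRMA is named in the submitters' processing notes, with no version. Each probe set appears to have been divided by a constant of its own, in a step that the sources used here do not give. In 30.6% of probe sets an array lies at exactly 1, and no subset of the 6 arrays has its median at 1 for more than 11.1% of probe sets, so the constant seems to come from a wider set of arrays. The linear scale follows from the values; the centring set is unknown. The direction of a difference between arrays does not depend on it. A ratio is no expression level: values cannot be compared between probe sets, no signal over background can be given, and the number of arrays limits the precision. The median ratio was 1.05, 1.02 and 0.877 on the control arrays and 1.02, 1.00 and 0.871 on the etanercept arrays of pairs 1, 2 and 3.

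The log2 of each deposited ratio was taken, with no floor or offset. GEO's platform annotation gave 1 gene for 19070 probe sets, several for 1043 and none for 2164. Symbols were updated through Entrez numbers with a RefSeq gene table (assembly GRCh38.p14, used for names only), which held 11954 of the 11963 genes. A gene's value was the mean log2 ratio of its probe sets, 19064 in all after controls were left out, with 4310 genes on over 1 probe set. No gene was left out for low values. The plan fixed before the data were examined had named the probe set with the highest mean and left out the lowest 40% of genes by mean; both rules presume expression levels. Once the values were seen to be ratios, and before any model was fitted, they were replaced as described. The original rules were kept as alternative settings, while no filter and averaged probe sets, first listed as alternative settings, became the main one.

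The groups were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) with the pair as a fixed block, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The block is in the main model because the labels state the pairing. The deviations from the group means correlated across genes at 0.790, 0.775 and 0.916 within pairs, against at most 0.325 between samples of different numbers. Pair accounted for 88.3% of the variance, treatment for 5.82% and the rest for 5.83%. No arrays were near duplicates: the SD of the log2 difference within pairs was 0.281, 0.214 and 0.218.

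Before the data were examined, 32 gene lists were fixed from textbook knowledge of monocyte-derived cells, TNF signalling and other blood cells. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. They were tested again with an estimated correlation and with fry, which asks whether a list's own genes move one way. With an estimated correlation camera also takes the residual degrees of freedom, 2 here, which leaves little power. For macrophage markers the estimated correlation was 0.00997, near the preset, yet the camera p went from 0.0158 to 0.137. A call lost in that setting therefore does not by itself show that correlation between members had made it. The estimated correlation was 0.015 for the phagocytosis list but 0.442 for the MHC class II list, far above the preset. Correlation between members could thus have made the MHC class II call. Members were also adjusted over the list alone. List means per pair were given an exact sign-flip permutation test, whose smallest two-sided p with 3 pairs is 0.25. Of the symbols listed, 742 were current, 15 were matched through older symbols and 2 had no match; genes not paired with a probe set of 1 gene were not analysed here.

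The genes named were fixed by rule: TNF and its receptors; the 12 strongest per direction past the threshold with 1 sign in all pairs, filled up where too few passed, in order of unadjusted p, with genes of 1 sign in all pairs and at least a 2-fold difference; and up to 4 members per list with the smallest p. Other members are named where they passed over their list alone or where a test rests on them.

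The fit was tested on simulated data. In 20 simulations of this comparison, over 11963 genes with 200 changed, it called 95.8% of 2-fold and 99.7% of 4-fold changes at a false share of 4.97%. The simulated noise was independent between genes and normal, with the fitted spread of variances. Each changed gene had the same change in all pairs, and its variance did not depend on the change. In the data SELENOP and CXCL8 had an SE of 0.36, against a median of 0.08 over all genes. The shares recovered therefore do not carry over to these data, and 0 calls do not mean that 2-fold changes are absent. Among lists with no shift 0.75% had p under 0.05, and all 20-gene lists shifted by 0.3 on the log2 scale were found. These lists were random genes with independent noise. Their shares therefore do not carry over to lists whose members vary together, such as MHC class II (estimated correlation 0.442).

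Alternatives covered no block, a random block, other filters and probe set rules, centring and quantile normalization of the arrays, a floor at the 25th percentile, a trended robust variance, array weights, a threshold of 0.10, and leaving out each pair. XIST and genes of the Y chromosome are not reported. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.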

Results

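Monocytes cultured with GM-CSF and IL-4 become immature dendritic cells, and the cultures compared here went through 5 days of that differentiation with or without etanercept. Transcripts of 11963 genes were measured on 6 arrays, 3 control and 3 etanercept, in 3 numbered pairs. The comparison asks which transcripts differ when etanercept, which binds TNF, is present during differentiation. How far TNF was neutralised was not measured on these arrays. The control titles name no other Fc protein, so effects of the Fc part cannot be told apart from those of TNF binding. Values are ratios to a constant of each probe set, so differences between arrays can be read and expression levels cannot. All gene changes below are etanercept minus control within pairs (n = 3 pairs).

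The largest differences with etanercept were higher values of genes that include members of the macrophage and the IL-4 and STAT6 lists. SELENOP, a secreted selenium transport protein, was 4.96-fold higher (95% interval 2.69 to 9.16). CCL18, a chemokine of IL-4-treated macrophages and dendritic cells, was 4.58-fold higher (3.07 to 6.83), and LGMN, the lysosomal cysteine protease legumain, 3.88-fold higher (2.87 to 5.25). CD163, the haemoglobin scavenger receptor, was 2.51-fold higher (1.87 to 3.37). On the other side, G0S2, an inhibitor of the lipase ATGL, was 2.64-fold lower, and the neutrophil chemokine CXCL8 was 2.29-fold lower. Each of these genes differed the same way in 3 of 3 pairs, but none passed the test over all genes. With ratios below the 25th percentile raised to it, G0S2 and CXCL8 lay at that floor on every array and showed no difference, and the log2 change was 0.49 for LGMN, 0.31 for CD163, 1.47 for CCL18 and 2.19 for SELENOP.

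No gene passed the limma test at an adjusted p of 0.05: the count was 0 higher and 0 lower, with a lowest adjusted p of 0.125. At an unadjusted p under 0.05 there were 1303 genes, 720 higher and 583 lower, where 598 would be expected by chance. The lowest adjusted p is shared by several genes, among them ABCA6, LGMN, ATP8B4, CCL18, CCL23 and G0S2, and 17 genes (16 higher, 1 lower) lay under 0.15. The pair weighs on this count: without pair 1 limma called 14 genes higher and 3 lower, without pair 2 it called 0 and 0, and without pair 3 it called 20 and 2. A trended robust variance gave 7 higher, quantile normalization 2, and leaving out the lowest 60% of genes by mean ratio 4; every other setting run, the planned probe set rule and filter among them, gave 0.

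Among the 12 genes named for the strongest rise in value, 2 are chemokines. CCL18 differed by 2.19 on the log2 scale (SE 0.23, limma adjusted p = 0.125), with a mean ratio of 2.05 ± 2.22 (SD) in control and 7.12 ± 5.52 in etanercept cultures. CCL23, a chemoattractant for monocytes that signals through CCR1, was 2.85-fold higher (log2 change 1.51, SE 0.16). Its log2 change ranged from 1.07 in pair 1 to 1.96 in pair 3. Both probe sets of CCL18 (2.16 and 2.23) and of CCL23 (1.54 and 1.48) gave like values.

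LGMN differed by 1.96 (SE 0.18), with pair values of 1.68, 2.52 and 1.66. SELENOP differed by 2.31 (SE 0.36, limma adjusted p = 0.231), and its pairs were uneven at 1.72, 1.70 and 3.52. CD163 differed by 1.33 (SE 0.17, limma adjusted p = 0.158); 2 of its 3 probe sets gave 2.36 and 1.57 and the other 0.06, so its value depends on the probe set. MS4A4A, a surface protein of macrophages and mast cells, was 2.10-fold higher and the matrix protein OLFML2B 2.38-fold higher (log2 change 1.25, and 0.73 with low ratios raised), with limma adjusted p of 0.328 and 0.316.

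ABCA6, a member of the ABCA family of lipid transporters, had the smallest p of all genes (log2 change 1.41, SE 0.11), and ATP8B4, a putative phospholipid flippase, was 2.19-fold higher (log2 change 1.13, and 0.56 with low ratios raised to the 25th percentile). P2RY14, the receptor for UDP-glucose, was 3.26-fold higher (limma adjusted p = 0.142), with pair values of 1.85, 2.20 and 1.06 on the log2 scale. ADORA3, the adenosine A3 receptor, was 2.12-fold higher and IPCEF1, which interacts with cytohesin exchange factors, 2.43-fold higher.

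**Figure D1:**
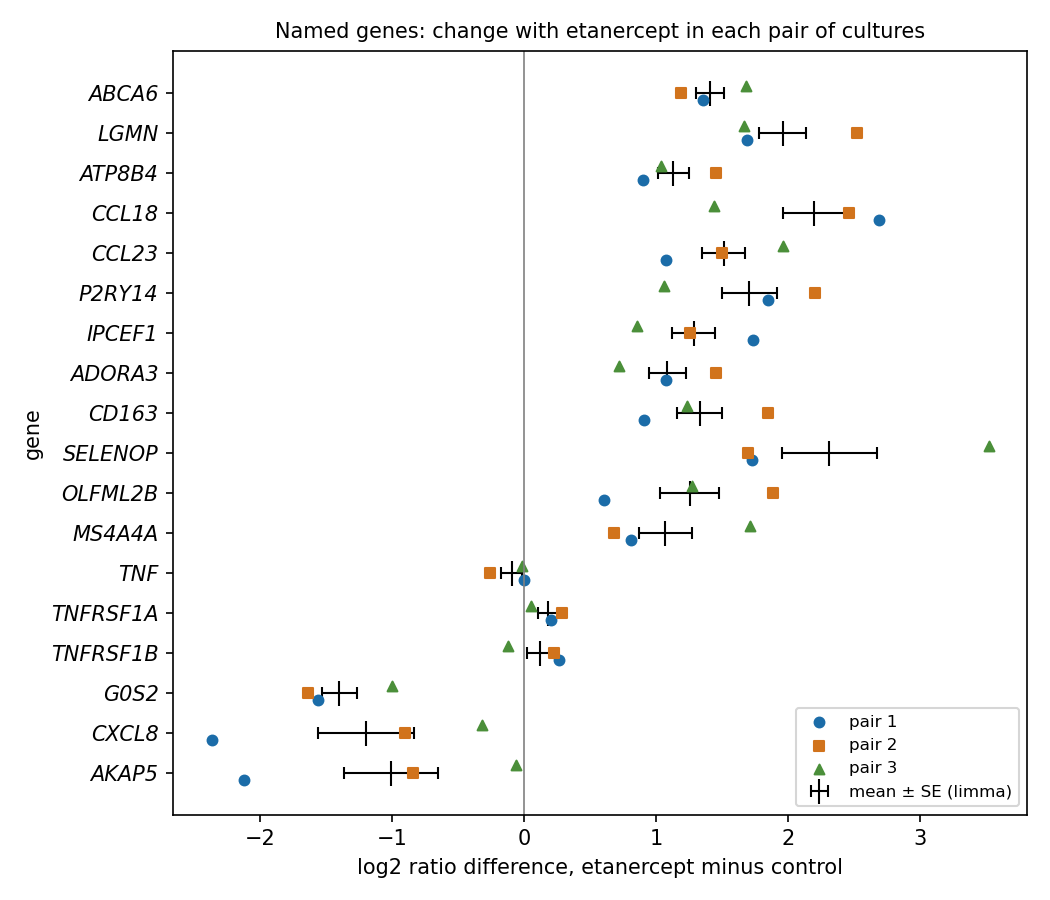
Difference in log2 ratio between etanercept and control (x axis) for the named genes and for TNF and its receptors (y axis), with a point for each of the 3 pairs and a black bar for the mean with its standard error from limma. SELENOP, CCL18 and LGMN stand at 2.31, 2.19 and 1.96, and G0S2, CXCL8 and AKAP5 at -1.40, -1.20 and -1.01; none passed the test over all genes.

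With 1 sign in all pairs and at least a 2-fold difference, 3 genes were lower, against 19 higher. G0S2 differed by -1.40 (SE 0.13, limma adjusted p = 0.125), with -1.56 and -1.64 in pairs 1 and 2 and a smaller difference in pair 3. CXCL8 differed by -1.20 (SE 0.36, limma adjusted p = 0.413), and AKAP5, a scaffold that anchors protein kinase A, by -1.01 (SE 0.36). Both rest mostly on pair 1, at -2.36 for CXCL8 and -2.12 for AKAP5, against -0.32 and -0.07 in pair 3. The transcript of TNF itself, the target of the drug, differed by -0.09 (SE 0.08), and by -0.01 without pair 2. Of its receptors, TNFRSF1A differed by 0.18 (SE 0.07) and TNFRSF1B by 0.12 (SE 0.10, with pair values of 0.26, 0.22 and -0.13); the receptor part of etanercept is a protein and adds no transcript.

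Of the gene lists fixed beforehand, camera at its preset correlation called 2, both higher with etanercept. Of the receptors for phagocytosis and pattern recognition, 17 of 23 measured were higher, 11 of them in all 3 pairs, with a median log2 change of 0.14 (camera adjusted p = 0.0014, and adjusted p = 0.934 with an estimated correlation). That median was 0.21 without pair 1, 0.10 without pair 2 and 0.11 without pair 3. Of the MHC class II presentation list, 16 of 17 members were higher, with a median of 0.09 (camera adjusted p = 0.0037, and adjusted p = 0.934 with an estimated correlation). Its estimated correlation was 0.442, against the preset 0.01, so correlation between members could have made this call. No member passed over all genes, and fry called 0 of the 32 lists (lowest adjusted p 0.410). Leaving out the lowest 40% or 60% of genes by mean ratio ended both calls. The planned probe set rule with its filter, leaving out pair 2, or leaving out the block ended that of MHC class II, whose camera adjusted p reached 0.332 over 14 settings.

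In the phagocytosis list, 7 members passed adjusted over the list alone, 6 higher and 1 lower, and 0 over all genes. The low-affinity IgG receptors led it, FCGR2B, the inhibitory one, at 1.72-fold higher (log2 change 0.78, SE 0.09) and FCGR2A, an activating one, at 1.66-fold higher (0.73, SE 0.15). Their sequences are close to each other, so the split between them is uncertain. TLR8 and RIGI, sensors of RNA, were 1.33-fold and 1.22-fold higher, and the scavenger receptor SCARB1 and LY96, the partner of TLR4, were 1.23-fold and 1.17-fold higher. The integrin chain ITGAM was the member that was lower, by a log2 change of -0.24.

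In the MHC class II list, 1 member passed adjusted over the list alone, and it was LGMN, which processes antigens in lysosomes and is no part of the MHC molecule. The others moved little: HLA-DQB1 differed by 0.28 (SE 0.08) and the peptide exchange chains HLA-DMB and HLA-DMA by 0.21 (SE 0.07) and 0.18 (SE 0.07). Probe sets for HLA genes can share sequence and meet donor differences, so HLA-DQB1 is uncertain. B cells also carry MHC class II, and their list had a mean log2 change of 0.40 in pair 3, against -0.09 and -0.05 in pairs 1 and 2. The MHC class II list had means of 0.14, 0.29 and 0.17 in the pairs. LGMN, at 1.68, 2.52 and 1.66, added the most to them, so they overstate the change of the other members (list median 0.09). Camera called the MHC class II list without pair 3 too (adjusted p = 0.0074, and 0.934 with all pairs and an estimated correlation). MHC class I presentation had 5 of 16 members higher and 11 lower (median -0.01, camera adjusted p = 0.933), and HLA-E, at 0.09, turned negative where each gene was read from 1 probe set.

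Macrophage markers did not pass as a list (camera adjusted p = 0.101; 13 of 24 higher, 11 lower, median 0.07). Adjusted over the list alone, 7 members passed. The higher ones were STAB1, a scavenger receptor also called stabilin-1 (1.77-fold), CD163, SELENOP, FCGR2A, the protease CTSL (1.41-fold) and the complement component C1QB (1.66-fold, with pair values of 0.74, 1.30 and 0.16 on the log2 scale), and the lower one was the apolipoprotein APOC1 (log2 change -0.36, and -0.23 without pair 2). IL-4 and STAT6 target genes had the same adjusted p of 0.101, with a median of 0.001 and a mean of 0.25, as CCL18, CCL23, STAB1 and GATM, an enzyme of creatine synthesis (1.30-fold higher), passed over the list alone while 10 of 21 members were lower. Camera called both lists without the block (adjusted p = 0.013 for macrophage markers and 0.040 for IL-4 targets), with a random block (0.0023 and 0.0032), without pair 1 (0.0042 and 0.0038) and without pair 3 (0.028 and 0.0074), but not with an estimated correlation (adjusted p = 0.934 for both). Over 14 settings the highest adjusted p of camera at its preset correlation was 0.506 and 0.469.

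Monocyte markers had 9 of 20 higher and 11 lower (median -0.02, camera adjusted p = 0.828). CD14, the lipopolysaccharide co-receptor, was 2.26-fold higher with pair values of 0.01, 1.29 and 2.23 on the log2 scale, while FCN1 differed by -0.50 (-0.26 without pair 1) and MPO by -0.27. Markers of monocyte-derived dendritic cells had 17 of 24 higher (median 0.06, camera adjusted p = 0.176), among them FCGR2B and the fatty acid carrier FABP4 (1.46-fold), which passed over the list alone, and the IgE receptor chain FCER1A (1.40-fold, log2 change 0.49, and 0.28 without pair 1), which did not; without pair 3 camera called this list (adjusted p = 0.0050), but not over all pairs with an estimated correlation (adjusted p = 0.934). Maturation and co-stimulation genes had 15 of 24 higher (median 0.05, camera adjusted p = 0.362), with the transcription factor STAT4 at 0.56 (SE 0.12), the ligand PDCD1LG2 at 0.39 (SE 0.12) and the actin bundler FSCN1 at -0.50 (SE 0.14), which were 0.22 and -0.29 without pair 3.

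NF-kB is the transcription factor through which TNF acts on many genes. Of its 24 target genes measured, 8 were higher and 16 lower, with a median of -0.15 (camera adjusted p = 0.273). With low ratios raised to the 25th percentile the median was 0 (camera adjusted p = 0.84). That floor removes any difference below it whatever the signal, so it cannot decide whether the lower values were real. TNFAIP6, given below, had mean ratios of only 0.08 in control and 0.06 in etanercept cultures. Adjusted over the list alone 7 passed, and over all genes 0. NFKBIA and NFKBIE, inhibitors of NF-kB that it induces itself, differed by -0.30 (SE 0.07) and -0.35 (SE 0.07), TNFAIP6 by -0.37 (SE 0.09) and CFLAR, an inhibitor of death receptor signalling, by -0.27 (SE 0.07), each lower in 3 of 3 pairs. MAP3K8, a kinase that acts downstream of TLR and TNF receptors, differed by 0.66 (SE 0.10), IER3 by 0.50 (SE 0.09) and the activation marker CD69 by 1.04 (SE 0.25, with pair values of 1.80, 0.35 and 0.97), each higher in 3 of 3 pairs.

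Lists of secreted mediators did not pass camera, nor fry for a shared direction. For change in either direction fry called the chemokine list and the TNF ligand, receptor and signalling list (adjusted p = 0.018 for each). Of 16 pro-inflammatory cytokines 10 were lower (median -0.08, camera adjusted p = 0.362), with INHBA, a subunit of activin A, at -0.36 (SE 0.10, and -0.23 without pair 2), IL1A at -0.27 (SE 0.10, and -0.15 without pair 1) and IL6 at 0.17 (SE 0.06). Of 23 chemokines 15 were lower; their median was -0.09 and their mean 0.07, since CCL18, CCL23 and CCL8 (2.11-fold higher) stood against CXCL8, and camera put the list lower and fry higher (camera adjusted p = 0.933). The anti-inflammatory list had 12 of 17 higher (median 0.03, camera adjusted p = 0.476), led by HMOX1, haem oxygenase 1, at 0.39 (SE 0.15) with pair values of 0.08, 0.86 and 0.24; without pair 1 its adjusted p was 0.046, and with all pairs and an estimated correlation 0.934. TNF ligands, receptors and signalling had 14 of 21 higher (median 0.05, camera adjusted p = 0.362), with TNFSF14 at -0.30 (SE 0.08) and IKBKB, a kinase that activates NF-kB, at 0.22 (SE 0.07).

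**Figure D2:**
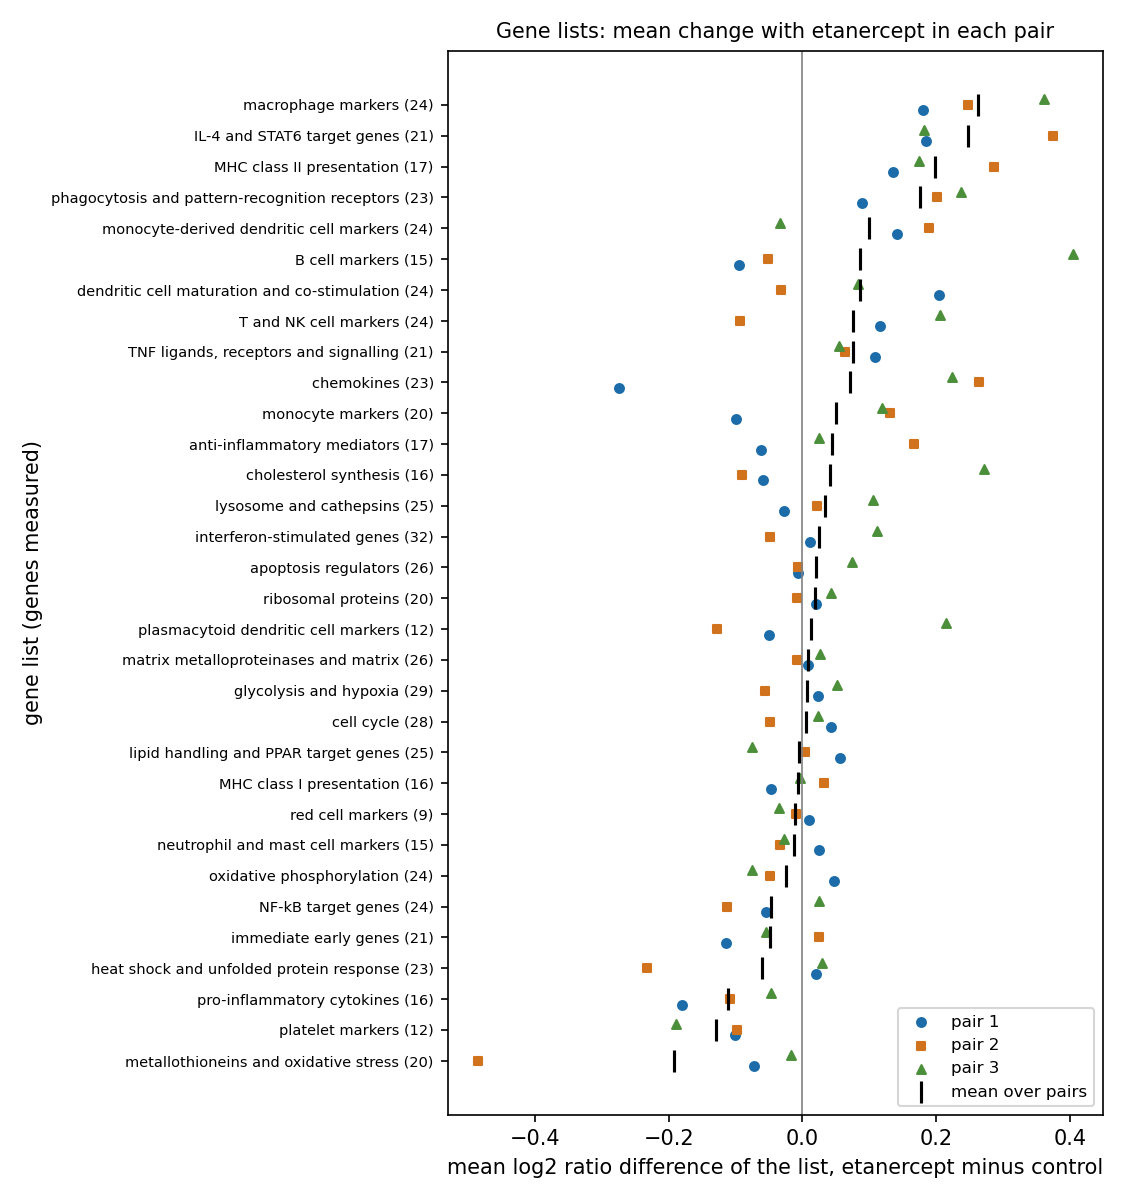
Mean difference in log2 ratio between etanercept and control (x axis) for each of the 32 gene lists (y axis, with the number of genes measured), with a point for each of the 3 pairs and a black bar for their mean. Macrophage markers have the highest mean, 0.26, and the B cell list spans -0.09 to 0.40; camera called the phagocytosis and MHC class II lists at its preset correlation only.

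Markers of other blood cells were read as a check on the cultures. T and NK cell markers had means of 0.12, -0.09 and 0.21 in the pairs (camera adjusted p = 0.362) and B cell markers those given above (camera adjusted p = 0.362, estimated correlation between members 0.89). Platelet markers had 11 of 12 lower, with means of -0.10, -0.10 and -0.19 (camera adjusted p = 0.101). Leaving out a pair made camera call the B cell list higher (without pair 1, adjusted p = 0.0038), the T and NK list higher (without pair 2, 0.030) and the platelet list lower (without pair 1, 0.046). With all pairs and an estimated correlation their adjusted p was 0.961, 0.961 and 0.934. No list mean could pass its exact sign-flip test over 3 pairs, whose smallest p is 0.25. The arrays of pair 3 stood apart from the other 4, with medians of 0.877 and 0.871. They shared 0 identical values with any of those, which shared 148 to 213 with each other. Their labelling controls had mean ratios of 0.79 and 0.77, against 0.98 to 1.06 on the others. Within pair 2 the hybridisation controls were at 0.65 in control and 0.82 in etanercept. What these technical differences did to gene values was not tested. The 3' minus 5' difference of the control probe sets, a measure of RNA integrity, changed by 0.00 ± 0.13 (SD over pairs) for GAPDH and 0.06 ± 0.18 for ACTB.

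The pairs resembled each other beyond single genes, though pairs 2 and 3 only weakly by rank. Across genes, which are not independent replicates, the Pearson correlation of the changes was 0.239 for pairs 1 and 2. It was 0.286 for pairs 1 and 3 and 0.235 for pairs 2 and 3. The Spearman (rank) correlations, in the same order, were 0.22137, 0.30234 and 0.10003. The Pearson value of pairs 2 and 3 may thus lean on genes with large changes. A sign shared by all 3 pairs was found in 4339 genes, or 36.3%, where 25% is the share by chance, and in at most 2866 when the sign of 1 pair was turned. Of those, 1924 were higher and 2415 lower; with arrays centred on their medians the split was 2535 higher and 1741 lower, so it depends on the centring, while the median change of all genes stayed small at -0.01 and 0.01.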

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

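The planned probe set rule and filter, and each of them alone, were run after the unit of the data was seen; all other alternatives were planned. The counts of genes past the limma test were 0 higher and 0 lower, and became 4 higher with the lowest 60% of genes by mean ratio left out, 2 with quantile normalization and 7 with a trended robust variance; the first of these tests fewer genes, and for the others the cause was not tested. Leaving out a pair gave 0 to 20 genes higher and 0 to 3 lower, with 3 genes called both without pair 1 and without pair 3. The fit with no replicate block called 0 higher and 0 lower, as did the random block. Of the 32 lists, 2 were called higher: 0 remained with camera at an estimated correlation and 0 with the lowest 40% or 60% of genes left out, 1 with the planned probe set rule and filter, 3 with no replicate block and 4 with a random block, where the list test ran on the moderated statistics. Leaving out a pair gave 2 to 7 lists higher and 0 to 2 lower; the cause was not tested. A threshold of 0.10, centring, array weights, the floor and the highest-mean probe set gave 0 genes in each direction and 2 lists higher. Among the 131 named genes, 3 of 1764 values changed sign, in HLA-E and RPL14, and 51 of 430 list directions did, none of them past the threshold. With the floor, G0S2 and CXCL8 lay below it on every array and have no difference there, while LGMN was at 0.49, ATP8B4 at 0.56, OLFML2B at 0.73 and CD163 at 0.31. With 1 probe set per gene CD163 was at 0.06. List members with low mean ratios in control and etanercept cultures are open to the same limit. Among them are BCL2A1 (0.04 and 0.05), TNFAIP6 (0.08 and 0.06), STAT4 (0.09 and 0.15) and CD14 (0.11 and 0.27). No filter and averaged probe sets are the main setting, so they give no separate values. The floor removes any difference below it whatever the signal, so a difference lost there is no sign of faint signal. Ratios hold no signal over background, so what faint signal limits cannot be given.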

Other observations

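Tests of the monocyte (with and without CD14), single-pair, B cell and lymphocyte explanations and of the 100 strongest genes were chosen after the changes were seen. Some lists not described above held single genes of interest. Among the immediate early genes, EGR1 differed by -0.51 (SE 0.07) with both probe sets lower, and passed adjusted over the list alone, while KLF4 stood at 0.44 (SE 0.11); 9 of 21 members were higher (camera adjusted p = 0.527). Among 32 interferon-stimulated genes, OAS1, which makes the activator of RNase L, was 1.58-fold higher and passed over the list alone, while IFIT2 and IFI27 stood at -0.23 and -0.18 (list median 0.02, camera adjusted p = 0.724). In lipid handling, PDK4 and FABP4 were 1.40-fold and 1.46-fold higher and passed over the list alone, LPL stood at 0.42 (0.27 without pair 2), and 15 of 25 members were lower (camera adjusted p = 0.933). The apoptosis regulators BCL2A1 and CASP4 stood at 0.37 (SE 0.07) and 0.30 (SE 0.09, and 0.19 without pair 3) and CFLAR at -0.27 (SE 0.07), with 17 of 26 members higher (camera adjusted p = 0.60). The matrix protein FN1 was 1.51-fold higher on average, with 4 of its 6 probe sets at 0.79 to 0.93 and the rest at 0.05 and -0.02, and the gelatinase MMP9 was 1.49-fold lower; the list's median was -0.02 and its mean 0.01 (camera adjusted p = 0.961).

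The metallothioneins MT1H and MT1X stood at -0.85 (SE 0.25) and -0.77 (SE 0.25), mainly from pair 2, with pair values for MT1X of -0.43, -1.59 and -0.28. Of the metallothionein and oxidative stress list, 0 members passed over the list alone. Its camera adjusted p was 0.321, 0.035 without pair 1, 0.0074 without pair 3, and 0.953 with all pairs and an estimated correlation. Near-identical sequences of metallothioneins make single members uncertain. Lysosomal genes had 15 of 25 higher (camera adjusted p = 0.499), with LAMP2 at 0.22. Lists of energy and growth moved little: the medians were -0.02 for oxidative phosphorylation, -0.04 for glycolysis and hypoxia, -0.01 for the cell cycle, 0.02 for ribosomal proteins, 0.06 for cholesterol synthesis and -0.05 for heat shock and unfolded protein response, with camera adjusted p of 0.582, 0.933, 0.933, 0.548, 0.476 and 0.476; without pair 1 that of cholesterol synthesis was 0.046, and with all pairs and an estimated correlation 0.961. For glycolysis and the cell cycle the means were above 0 (0.01 and 0.01). Plasmacytoid dendritic cell, red cell and neutrophil and mast cell markers had medians of 0.02, -0.11 and -0.04 (camera adjusted p = 0.933, 0.582 and 0.588). Tested for change in either direction, fry called 8 of the 32 lists (lowest adjusted p 0.018). These were the NF-kB, TNF signalling, chemokine, monocyte-derived dendritic cell, IL-4 and STAT6, monocyte, apoptosis and immediate early lists.

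Other splits of the 6 arrays into 3 and 3 were fitted with the block. At an unadjusted p under 0.05 the real split gave 1303 genes and the highest of the others 1531, so 3 of the 10 splits gave as many. Both splits with 1531 part only pair 1 and keep the other pairs whole, so with the block they are the same fit. A split that parts 1 pair takes its contrast from that pair alone. Its residual holds the treatment difference of the other pairs, so it is no null for this comparison. Among the splits that part all 3 pairs, the real one gave the most genes, 1303 against 314, 491 and 247. Of the lists, the real split called 2 and the highest other, which also parts all 3 pairs, 12, and 8 of the 10 splits called 2 or more. The others that part all 3 pairs called 7, 2 and 12 lists. At an adjusted p under 0.05 all 10 splits called 0 genes. With 10 splits no share can go under 0.05, and among those that part all 3 pairs none can go under 0.25. Shares over all 10 count the same fit more than once, so they cannot decide whether chance gave these counts.

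The 10 named genes with the strongest evidence for higher values, from ABCA6 to SELENOP, include CD163 and SELENOP of the macrophage list. A difference in RNA quality as the cause in all pairs is argued against, since the 3' minus 5' difference of GAPDH and ACTB went up in pair 1 (0.15 and 0.27) and down in the others (mean of all 0.0288), while these genes were higher in each pair; a part in pair 1 stays open. A single pair carrying the change is argued against too: 10 genes chosen from 2 pairs alone by evidence for a rise, at most 2 of them in the macrophage list, had a median log2 change in the pair left out of 0.753, 1.60 and 0.958, with 10, 10 and 9 of 10 higher there. Monocytes that had not differentiated could add CD163, and this cannot be told apart. The 19 monocyte markers outside the other lists had a mean of -0.0168 (SE over members 0.078), which rests on CD14, with pair means of -0.15, 0.04 and 0.06. Without CD14 the mean was -0.08 (SE over members 0.043, 7 higher, 11 lower), with pair means of -0.16, -0.03 and -0.06. That is short of the bound set for excluding such monocytes. The bound uses the SE over members, which may vary together and are no replicates, so it does not measure the spread over pairs. LYZ stood at 0.07, S100A8 and S100A9 at 0.08 and 0.16 but not higher in every pair, and FCN1 at -0.50 (-0.26 without pair 1). Among the 100 genes with the smallest p of those higher in all 3 pairs, the macrophage list held 4 where 0.20 were expected (Fisher's exact test, adjusted p = 0.00137) and the IL-4 and STAT6 list 3 (adjusted p = 0.0144), with STAB1 in both; members of these lists had been seen to lead the ranking and camera did not call either list (adjusted p = 0.101 for both), so whether macrophage genes as a class were higher stays open.

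The NF-kB targets that passed over their list alone went both ways, NFKBIA, NFKBIE, TNFAIP6 and CFLAR lower and MAP3K8, IER3 and CD69 higher. Scaling between arrays is argued against, since 7 of the 7 kept their side of the threshold and their sign both centred and quantile normalized. RNA quality as the cause in all pairs is argued against by the same differences (mean 0.0288), which went both ways over the pairs while each of these genes kept its sign, and a part in pair 1 stays open. The list held 4 of the 100 genes with the smallest p of those lower in all 3 pairs (Fisher's exact test, adjusted p = 0.00137) and 2 of the 100 on the higher side (adjusted p = 0.147), while camera did not call it (adjusted p = 0.273). With low ratios raised to the 25th percentile the list's median change was 0, which cannot decide the matter, since the floor removes any difference below it. No biological explanation was tested.

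B cell markers were higher in pair 3 alone, by a mean log2 change of 0.405, with POU2AF1 at 0.88, BANK1 at 0.83, JCHAIN at 0.73 and MS4A1 at 0.71. That mean lay at percentile 100 of 10000 random lists of the same size, and the T and NK list at percentile 99.97 there with a mean of 0.205. The B cell rise was seen before its percentile was taken, and both rest on 1 control and 1 etanercept array. The percentile thus restates the rise and is no separate support. B cells or lymphocytes in general, or their RNA, in the etanercept culture of that pair are a candidate source that these values cannot decide on. Members of a list vary together, so these percentiles overstate how far it stands out, and the T and NK list reached percentile 97.77 in pair 1 and 1.75 in pair 2. The plasmacytoid list lay at percentile 99.75 in pair 3 and 1.68 in pair 2. It shares TCL1A, which differed by only 0.04 in pair 3, with the B cell list, and GZMB with the T and NK list. The labels name no sort or gate. Whether the treatment or the cell preparation brought the values in pair 3 about was not tested.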
